A study of Mus musculus with 2 samples.

How the data were processed

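The series holds 2 droplet single-cell RNA libraries, 1 per group, from T cells sorted as CD4 and CD8 positive out of lung tumours, 8 weeks after intranasal adenoviral Cre. WTKL came from mice with Tmem173-floxed bone marrow and LYZKL from mice with Tmem173-floxed, Lyz2-Cre bone marrow. The treatment label of WTKL also names tamoxifen and that of LYZKL does not. The matrices deposited by the authors hold raw UMI counts, whole numbers per gene and barcode. Cell Ranger 6.1.2 and mm10 made them, per the submitters' processing notes. The other deposited files hold gene identifiers and cell barcodes, which are labels with no other unit.

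The WTKL matrix has 12204 barcodes where the labels state 6609 cells, and the LYZKL matrix 13607 where they state 7202, with 10000 cells targeted in each. No barcode has fewer than 500 UMIs in WTKL or 501 in LYZKL, so a minimum had been applied. The barcodes are 17 bases long. Total UMIs were 77181312 and 93584629 over 32285 genes.

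Cells were kept with at least 500 detected genes and at most 10% mitochondrially coded UMIs, which removed 170 and 31 barcodes in WTKL and 121 and 35 in LYZKL. Predicted doublets were removed per library with Scrublet as built into scanpy. Its automatic threshold marked no cells in WTKL, where the highest scores were removed at a preset rate of 0.8% per 1000 cells (1153 cells, 9.61%), and 435 cells (3.23%) in LYZKL. The kept cells number 10850 and 13016, with a median of 4677 and 5236.5 UMIs per cell.

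Counts were normalized to 10000 per cell and log-transformed. Clusters came from 2000 variable genes without receptor and immunoglobulin segment, mitochondrially coded, ribosomal protein and sex-linked genes, 30 principal components, 15 nearest neighbours and Leiden resolution 1, with no integration of the libraries. This gave 22 clusters: 11 T-lineage, 9 other and 2 mixed. The labels name no cell types beyond T cells, so the names were rebuilt from markers of 20 classes and carry the ending -like. A cluster was left unnamed where its 10 leading genes hold more markers of another class. The thresholds for naming, such as a geometric mean of 250 CPM of 7 T cell markers, were set after seeing the data. Cluster 3 is 79.1% LYZKL cells, so it may in part describe that library.

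UMIs were summed per library and class and scaled by the total of the class to CPM. Intervals of counts are exact Poisson intervals, those of shares exact Clopper-Pearson intervals, those of ratios of shares come from the Katz log method, and those of CPM ratios from the exact conditional binomial, all at 95%. The 24 gene lists were Treg identity and effector, NAD metabolism and P2X7, pro-apoptotic, survival, exhaustion and checkpoint, cytotoxicity, naive and central memory, type I interferon response, interferon gamma response, tissue residency, Th1, Th2, Th17, Tfh, T cell activation, immediate early and heat shock, STING pathway, homing receptors, cell cycle, glycolysis, oxidative phosphorylation, ribosomal proteins, mitochondrially coded and sex-linked genes. For each list the median log2 ratio over members with at least 5 CPM was computed, with its percentile among 10000 random lists of the same size matched in 20 expression bins. Symbols of 4 list entries were absent from the matrix.

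Named genes were, per class, the 10 highest and 10 lowest log2 ratios among genes with at least 30 CPM in the higher library and 100 UMIs over both, without receptor and immunoglobulin segment, mitochondrially coded, ribosomal protein and sex-linked genes and unnamed gene models. List members of at least 30 CPM served as examples, and 16 genes were always named. A library at 0 was set to a floor of 3 counts. Some genes that this rule selects are not reported here. The filter on unnamed gene models was widened after the data were seen, because an accession-like name had passed it. Lists, markers, filters, the rule for named genes and the alternatives listed first below were fixed before the data were examined. Genes named for macrophage-, neutrophil- and B-like cells follow the same rule, applied to those classes after the data were seen.

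The alternatives were other minimums of detected genes (200 and 1000), other mitochondrial limits (5% and 20%), doublets kept, Leiden resolutions of 0.5 and 2, 4000 variable genes, 15 principal components, another seed, each library clustered alone, classes from marker UMIs, the mean of per-cell CPM, edgeR TMM scaling, a total without ribosomal protein and mitochondrially coded genes, and other minimums of list genes (none and 20 CPM). Added after the data were seen were doublets removed at the preset rate in both libraries, unnamed clusters counted with their closest class, CD8-like clusters taken singly, and clusters made without 53 leading genes that differ by 1.5-fold between the libraries.

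The CPM ratios were tested on data simulated for 1 comparison only, that of cells with a Foxp3 UMI in the 2 libraries: planted changes of 1.5-, 2- and 4-fold had the right direction in 100% of genes, their intervals held the planted value in 91.2%, 94.1% and 93.8% of genes, and 3.50% of null lists lay outside the central 95% of random lists. The simulated counts were Poisson draws from a single pooled profile, the model that the intervals assume. They held no spread between mice or cells, so this checks the calculation only. Gene coordinates from the GENCODE annotation of GRCm38 matched 32158 of 32285 gene identifiers (99.6%). The software was Python 3.11.15, scanpy 1.11.5, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9, leidenalg 0.10.2, matplotlib 3.10.9 and edgeR 4.0.16.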

Results

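Both libraries hold cells sorted from lung tumours of mice whose own cells carry floxed Lkb1 alleles, and whose blood system was replaced by donor bone marrow. The donors of WTKL carried floxed Tmem173 alleles, and those of LYZKL also carried Lyz2-Cre, a recombinase expressed in the myeloid lineage. Tmem173 codes for STING, the adaptor of the cytosolic DNA sensing pathway. The series title raises the question of how STING and CD38 in macrophages bear on the survival of regulatory T (Treg) cells. With 1 library per group no test between groups is possible, so no p-value is given, and every interval below covers counting error only, not the spread between mice.

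Tmem173 was lower in the library labelled LYZKL in neutrophil-like cells (18.6 CPM, UMIs scaled by the total of the class, in WTKL and 4.92 in LYZKL, log2 ratio -1.92, 95% interval -2.46 to -1.40) and slightly lower in macrophage- or monocyte-like cells (41.9 and 33.7 CPM, log2 ratio -0.31, -0.49 to -0.14). In lymphocytes it was higher in LYZKL: 33.6 and 84.5 CPM in Treg-like cells (2.51-fold), 21.1 and 43.9 CPM in CD4 conventional-like cells (2.09-fold) and 21.5 and 39.7 CPM in B-like cells (1.85-fold). CD8-like cells had 35.1 and 36.5 CPM, a log2 ratio of 0.054 (-0.15 to 0.26). The gene lies on chromosome 18 of GRCm38 (mm10), from 35733679 to 35740554. The labels do not say which exons are floxed, and 3' tags from outside a deleted part would still be counted, so these levels do not check the deletion. Within neutrophil-like clusters, Tmem173 was at 35.1 and 5.82 CPM in cluster 12 (64 and 4 UMIs), at 8.11 and 4.14 CPM in cluster 4 (15 and 24 UMIs, log2 ratio -0.97, -1.96 to 0.064) and at 12.5 and 6.39 CPM in cluster 11 (22 and 17 UMIs, log2 ratio -0.97, -1.97 to 0.013).

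**Figure D1:**
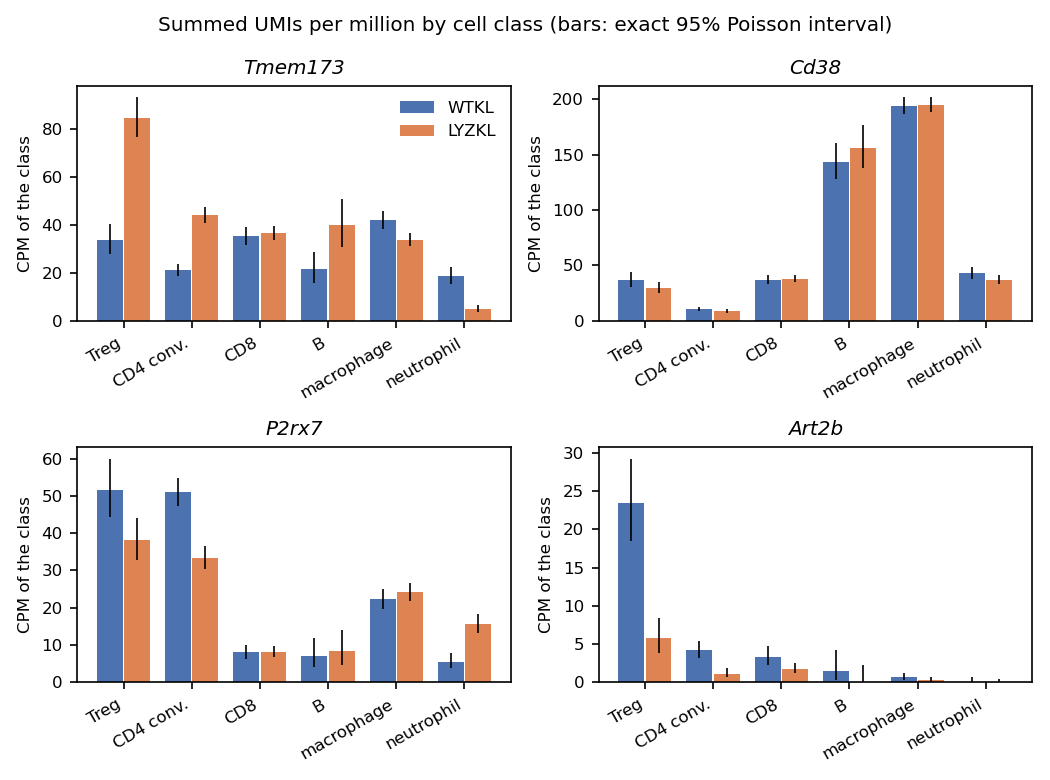
Summed UMIs scaled by the total of the class (CPM, vertical axes) of Tmem173, Cd38, P2rx7 and Art2b in 6 cell classes of the WTKL and LYZKL libraries, 1 library each; error bars are exact 95% Poisson intervals of the counts. Tmem173 stands at 33.6 CPM in WTKL and 84.5 CPM in LYZKL in Treg-like cells, and Cd38 at 194 and 195 CPM in macrophage- or monocyte-like cells.

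Treg-like cells made up a like share of T-lineage cells in both libraries, 633 of 7872 cells (8.04%) in WTKL and 735 of 8764 (8.39%) in LYZKL, a ratio of 1.04 (0.942 to 1.15). CD8-like cells were 20.4% in WTKL and 35.3% in LYZKL (ratio 1.73, 1.64 to 1.82), CD4 conventional-like cells 36.6% and 26.8% (0.733, 0.701 to 0.767), and cycling-like cells 3.32% and 5.34% (1.61, 1.39 to 1.87). As a share of the Treg-like cluster and all clusters closest to CD4 conventional T cells, Treg-like cells were 11.2% and 14.2% (1.28, 1.15 to 1.41). These clusters include the unnamed cluster 2 (1560 and 1565 cells), led by Il17a and Il17f, whose leading genes hold more gamma-delta T cell markers. The unnamed cluster 9 is among them too, and its leading genes hold more Treg markers. It held 7.58% and 5.84% of T-lineage cells (ratio 0.770) and is not counted as Treg-like in the shares above. With at least 1000 detected genes, the cluster that held most of its cells was named Treg-like. Cells with at least 1 UMI of Foxp3, the Treg lineage factor, were 5.04% and 5.87% of T-lineage cells after thinning to 2000 UMIs (7.43% and 8.79% unthinned, median depths 4824 and 5505.5 UMIs). In CD8-like cells, which should lack Foxp3, the thinned share was 0.459% and 0.280% (median depths 5165.5 and 4330 UMIs). Thinning left out 329 and 414 T-lineage cells.

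The cells were sorted as CD4 and CD8 positive, and the sort can set the proportion of CD8-like to CD4-type cells and the share of other cells. T-lineage clusters that took no name held 31.6% of T-lineage cells in WTKL and 24.2% in LYZKL, and counting them with their closest class gives a CD8-like log2 ratio of 0.54 in place of 0.79. The CD8-like ratio turned below 1 under 4 alternatives in which most cells of the main CD8-like cluster lost their name, in 3 of them because the leading genes held more gamma-delta T cell markers. With each library clustered alone, most of these cells lost their name in LYZKL but not in WTKL. The Treg-like share of T-lineage cells had a ratio below 1 in 4 of 14 alternatives: at least 1000 detected genes (log2 ratio -0.13), up to 20% mitochondrial UMIs (-0.10), the preset doublet rate in both libraries (-0.041) and doublets kept (-0.0052).

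**Figure D2:**
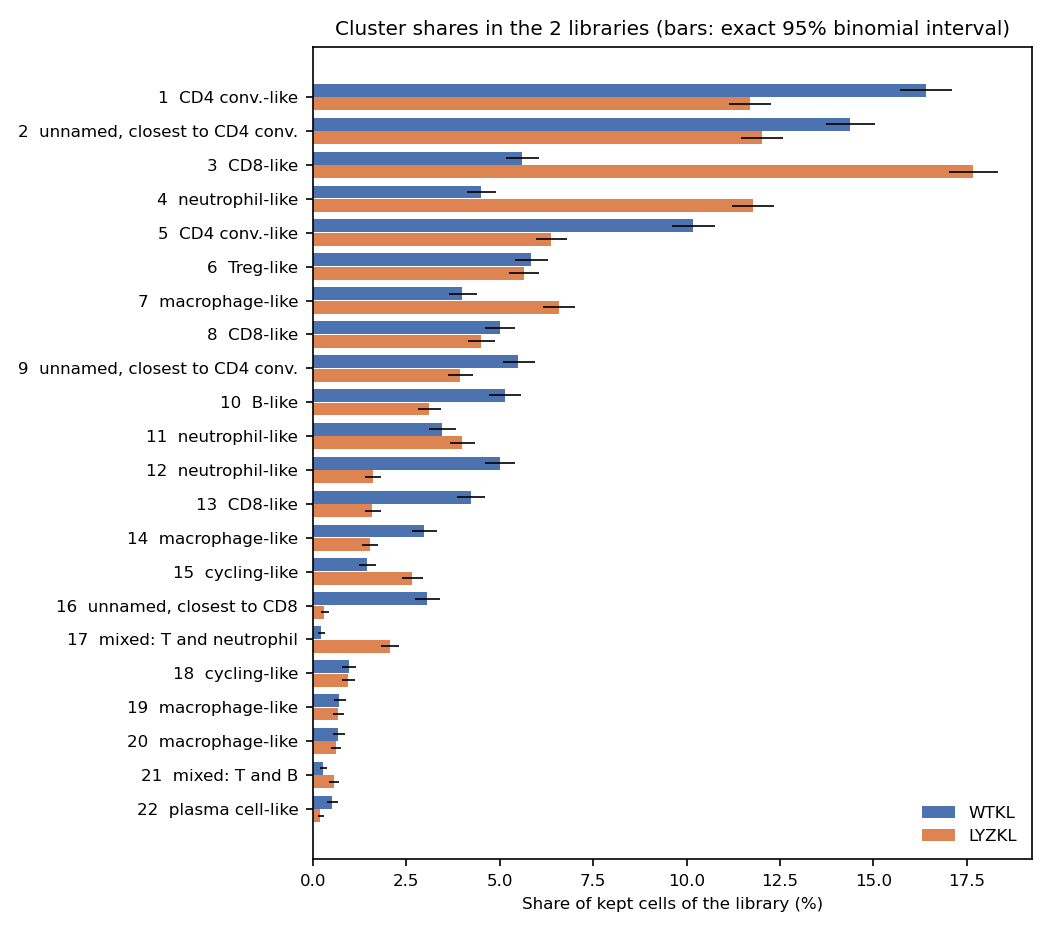
Share of kept cells (horizontal axis, percent) in each of 22 clusters of the WTKL and LYZKL libraries, with exact 95% binomial intervals. Cluster 3, CD8-like, held 5.60% of WTKL and 17.7% of LYZKL cells, and cluster 6, Treg-like, 5.83% and 5.65%.

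In Treg-like cells 20 of 21 measured genes of the interferon gamma response list were higher in LYZKL, 13 of them by at least 1.5-fold, with a median log2 ratio of 0.63 (0.52 to 0.71). Iigp1, an interferon-inducible GTPase, stood at 113 CPM in WTKL and 252 CPM in LYZKL, and the guanylate-binding proteins Gbp3 and Gbp2 at 110 and 215 CPM and at 124 and 224 CPM. The type I interferon list had 23 of 24 genes higher (median 0.49, 0.37 to 0.63), among them Rtp4 (21.9 and 46.9 CPM), Xaf1 (21.3 and 42.5 CPM) and Zbp1, a nucleic acid sensor (70.0 and 132 CPM).

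Effector genes of Treg-like cells went both ways. The cytotoxicity list had a median of 0.62 (0.42 to 0.75) with 11 of 16 genes higher: Ifng, which codes for interferon gamma, was at 8.71 and 32.1 CPM, the chemokines Ccl4 and Ccl3 at 32.1 and 90.1 CPM and at 22.5 and 43.8 CPM, and Gzmb, granzyme B, at 179 and 310 CPM, while Klrg1, a receptor of terminally differentiated cells, was lower (109 and 70.9 CPM). Ccl3 is also a leading gene of the neutrophil-like cluster 4 (4.50% of kept cells in WTKL and 11.8% in LYZKL). Both chemokine genes lead cluster 17 (0.212% and 2.06%), which carries T cell and neutrophil markers. RNA from such cells as a cause of the chemokine values in Treg-like or CD8-like cells was not tested. Nor was RNA from CD8-like cells tested for the Ifng and Gzmb values in Treg-like cells. Exhaustion and checkpoint genes were lower in 9 of 13 cases (median -0.30, -0.54 to -0.081), including Rgs16 (181 and 85.9 CPM), Tox (564 and 351 CPM) and Pdcd1, which codes for the PD-1 receptor (161 and 100.3 CPM). All 10 measured genes of the naive and central memory list were higher (median 0.30, 0.23 to 0.38), such as the lymph node homing receptor Ccr7 (95.5 and 160.0 CPM). The Th1 list had a median of 0.32 (-0.0064 to 0.41). Signs of handling and RNA quality differed beside these genes: immediate early and heat shock genes were lower in 16 of 18 cases (median -0.27, -0.34 to -0.23), with Egr1 at 117 and 69.4 CPM, and mitochondrially coded genes in 13 of 13 (median -0.21, -0.25 to -0.13). Their share in the interferon and effector values was not tested.

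The Treg identity and effector list had 14 genes higher and 12 lower (median 0.037, -0.017 to 0.094): Foxp3 was at 390 and 469 CPM, Il2ra, the interleukin 2 receptor alpha chain, at 540 and 680 CPM, Ctla4 at 3276 and 3515 CPM, Il10 at 97.0 and 152 CPM and Nrp1 at 175 and 111 CPM. The survival list had 8 of 13 genes higher (median 0.066, 0.012 to 0.14), with Bcl2 at 119 and 140 CPM and Mcl1 at 305 and 298 CPM. The pro-apoptotic list had 8 higher and 10 lower (median -0.050, -0.12 to 0.063), with Bcl2l11, which codes for BIM, at 30.04 and 38.4 CPM. The list of NAD metabolism and P2X7 had 8 of 13 genes lower (median -0.20, -0.28 to 0.059). In it P2rx7, the ATP-gated channel, was at 51.7 and 38.2 CPM, Art2b, the ADP-ribosyltransferase that acts on it, at 23.4 and 5.84 CPM, and Cd38, an NAD-consuming enzyme, at 36.6 and 29.4 CPM (log2 ratio -0.32, -0.68 to 0.044). Among 10000 random lists matched on expression the NAD list lay at percentile 2.03, the pro-apoptotic list at 26.9, the survival list at 82.1 and the identity list at 72.7, which describes these libraries only. In T-lineage cells with a Foxp3 UMI, Foxp3 (log2 ratio -0.017) and Gzmb (-0.19) turned direction, and the identity list had a median of -0.034.

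Among the genes named here, the largest single differences in Treg-like cells, those of Jchain, Slpi and Pcsk1, were lower values in LYZKL. Jchain, which codes for the joining chain of immunoglobulin A and M, was at 588 CPM in WTKL and 15.6 CPM in LYZKL (37.6-fold lower), Slpi, a secreted protease inhibitor, at 75.4 and 10.6 CPM and Pcsk1, a prohormone convertase, at 69.4 and 13.6 CPM. Nav2, Nckap5, Nrn1, Frmd5, Tex14 and Ttc28 were lower by 2.06- to 2.81-fold, while Ifng, Ccl4 and Tmem173, given above, were higher. Jchain was also lower in CD4 conventional-like cells (155 and 16.7 CPM) and in B-like cells (169 and 60.8 CPM), and higher in macrophage- or monocyte-like cells (28.6 and 59.4 CPM). Plasma cell-like cells, its main source, were 0.516% of kept cells in WTKL and 0.1998% in LYZKL. Whether plasma cell RNA or a few cells carry the Jchain values of the other classes was not tested.

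**Figure D3:**
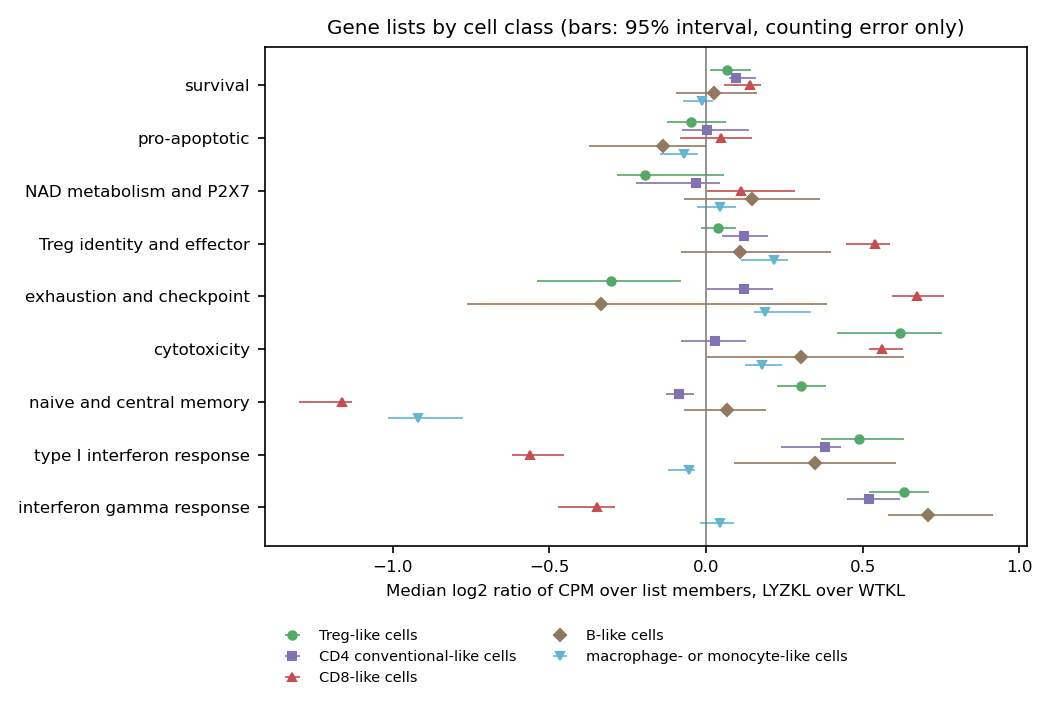
Median log2 ratio of CPM, LYZKL over WTKL (horizontal axis), over the members of 9 gene lists in 5 cell classes, 1 library per group; bars are 95% intervals from counting error. The interferon gamma response list stands at 0.63 in Treg-like, 0.52 in CD4 conventional-like, 0.71 in B-like and -0.35 in CD8-like cells.

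Summed over the class, CD8-like cells of LYZKL had more transcripts of checkpoint and effector genes and fewer of naive genes. The clusters in the class differ in share between the libraries, and within them these shifts were smaller or absent, as given below. The class leaves out the unnamed cluster 16, closest to CD8 T cells and led by Gzmb, Gzma and Klrg1. That cluster had 331 cells in WTKL and 40 in LYZKL, and the lists were not recomputed with it, so the effector values do not cover all CD8-type cells. All 14 exhaustion and checkpoint genes were higher (median 0.67, 0.59 to 0.76), with the receptors Havcr2 at 31.3 and 71.3 CPM and Pdcd1 at 144 and 287 CPM and the transcription factor Tox at 146 and 269 CPM. Of 16 cytotoxicity genes 15 were higher (median 0.56, 0.52 to 0.63), such as Ccl3 (167 and 550 CPM), the activating receptor Klrk1 (151 and 381 CPM) and Ifng (261 and 459 CPM), while Gzmb was at 445 and 428 CPM. With each library clustered alone, Ccl3 in CD8-like cells (log2 ratio -1.11) and Ifng in CD8-like cells (-0.47) turned direction. In that setting 2.47% of the WTKL cells and 85.8% of the LYZKL cells of cluster 3 lay in unnamed clusters, so the class compares unlike cells. All 11 naive and central memory genes were lower (median -1.16, -1.30 to -1.13), with Igfbp4 at 353 and 109 CPM and Ccr7 at 152 and 57.0 CPM. Interferon response genes were lower too: 21 of 24 on the type I list (median -0.56, -0.62 to -0.45), with Ifit3 at 46.9 and 16.1 CPM, and 16 of 21 on the interferon gamma list (median -0.35, -0.47 to -0.29). Mitochondrially coded genes were lower in 10 of 13 cases (median -0.21, -0.25 to -0.16) and ribosomal protein genes in 82 of 92 (median -0.17, -0.18 to -0.16). RNA quality as a cause was not tested.

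Among genes outside the lists, Gzmc, a granzyme, was at 6.40 and 62.1 CPM in CD8-like cells, the kinase-like Styk1 at 8.46 and 42.6 CPM, the killer lectin-like receptor Klri2 at 12.3 and 54.0 CPM, the cytokines Csf1 at 27.1 and 97.0 CPM and Tnfsf11, which codes for RANKL, at 45.1 and 146 CPM. Schip1, Nrn1, Dscam and Raph1 were higher by 3.16- to 3.39-fold. The interleukin 6 receptor chains Il6ra (45.6 and 14.8 CPM) and Il6st (73.0 and 27.8 CPM) were lower, as were Txk, Cd55, Gpr18 and Actn1, by 2.68- to 2.88-fold. With each library clustered alone, the log2 ratio of Styk1 in CD8-like cells was -0.10. There most cells of cluster 3 left the class in LYZKL but not in WTKL, so unlike cells are compared.

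The make-up of the CD8-like class differed. Cluster 3, with the gamma-delta T cell receptor genes Tcrg-C2 and Trgv2 beside Xcl1, Klrk1 and Cd8a among its 10 leading genes, so that its CD8 name is in doubt, held 37.8% of CD8-like cells in WTKL and 74.4% in LYZKL, the Eomes and Gzmk expressing cluster 8 held 33.7% and 18.95%, and the naive-type cluster 13 held 28.5% and 6.69%. Within these clusters the cytotoxicity medians were 0.089, 0.066 and 0.13 and the exhaustion and checkpoint medians 0.073, 0.38 and 0.087, each below the value of the whole class. In the same order the naive and central memory medians were -0.37, -0.24 and 0.049, the type I interferon medians -0.40, -0.50 and -0.26, and the interferon gamma medians -0.31, 0.046 and -0.10. The naive and interferon gamma shifts of the class thus do not hold in every cluster. The cytotoxicity and naive shifts, and the exhaustion shift outside cluster 8, were far smaller within clusters than in the class, whose make-up differed. Klrk1 and Klri2, given above, are among the 10 leading genes of cluster 3. TMM scaling would shift all log2 ratios in CD8-like cells by -0.13.

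**Figure D4:**
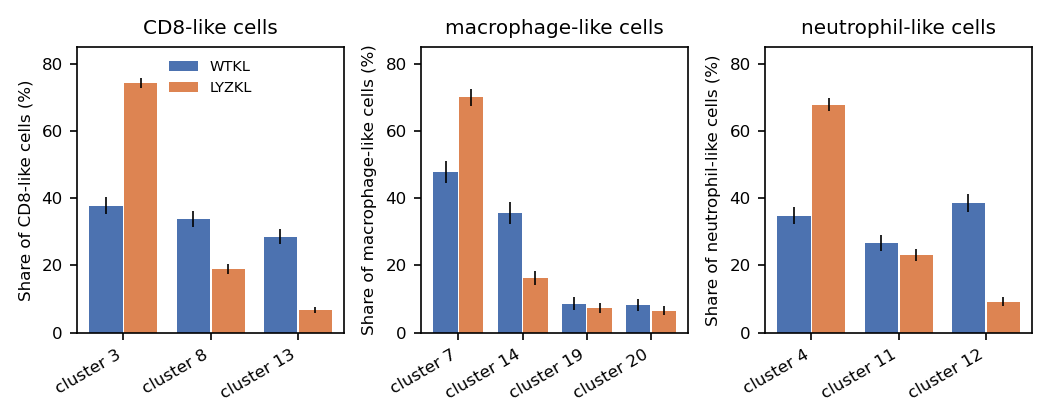
Share of each class (vertical axes, percent) held by its clusters among CD8-like, macrophage-like and neutrophil-like cells of the WTKL and LYZKL libraries, with exact 95% binomial intervals. Cluster 3 held 37.8% and 74.4% of CD8-like cells, cluster 7 held 47.8% and 70.0% of macrophage-like cells, and cluster 4 held 34.7% and 67.8% of neutrophil-like cells.

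In CD4 conventional-like cells 19 of 21 interferon gamma response genes were higher in LYZKL (median 0.52, 0.45 to 0.62), with Iigp1 at 39.9 and 110 CPM, Gbp5 at 26.6 and 59.7 CPM and Gbp2 at 73.9 and 149 CPM, and 17 of 23 type I interferon genes were higher (median 0.38, 0.24 to 0.43). The interferon gamma medians were 0.45 and 0.78 in clusters 1 and 5 of this class, and 0.16 and 0.10 in the unnamed clusters 2 and 9, which lie closest to it. The type I medians were 0.46 and 0.25, and 0.25 and -0.094. Il22, a cytokine that acts on epithelium, was at 92.5 and 270 CPM, the interferon-inducible chemokine Cxcl10 at 46.2 and 98.4 CPM, and Ifng at 21.3 and 35.7 CPM. The Th1 list had 7 of 8 genes higher (median 0.33, 0.21 to 0.41) and the Th17 list 5 of 8 (median 0.16, 0.10 to 0.22). Th17 medians were 0.12 and -0.24 in clusters 1 and 5 and -0.12 and 0.18 in the unnamed clusters 2 and 9. Neb, Il1r2, H1f0 and Mpp7 were higher by 1.90- to 2.501-fold. Besides Jchain, lower genes included Tox (101 and 53.1 CPM), Camk2n1, Igflr1, Acyp1, St3gal6, Acvr2a, Krt83, Rdm1 and Tex14, by 1.80- to 2.21-fold. P2rx7 was at 51.1 and 33.4 CPM, and the survival list had 12 of 14 genes higher (median 0.096, 0.074 to 0.16).

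Macrophage- or monocyte-like cells were 8.37% of kept cells in WTKL and 9.39% in LYZKL, and neutrophil-like cells 12.9% and 17.4%, shares that measure what passed the sort. Cd38 was alike in macrophage- or monocyte-like cells, 194 and 195 CPM (log2 ratio 0.0059, -0.070 to 0.082). The chemokine genes Ccl17 (292 and 71.3 CPM), Ccl8 (85.1 and 17.98 CPM) and Cxcl13 (38.3 and 5.77 CPM) were lower in LYZKL, and Prg4, which codes for lubricin (8.18 and 35.1 CPM), Mfge8, a bridging protein for the uptake of dying cells (27.7 and 62.7 CPM), and Ctsk, cathepsin K (129 and 231 CPM), were higher. Cluster 7, which expresses Cfb, Saa3 and Nos2, held 47.8% and 70.0% of these cells, and cluster 14, which expresses Ccl17 and Vcan, 35.6% and 16.2%. T cell transcripts in these cells moved as well: naive and central memory genes were lower in 10 of 11 cases (median -0.92, -1.01 to -0.78), for example Igfbp4 (53.8 and 20.7 CPM) and Lef1 (34.9 and 17.02 CPM). The cytotoxicity, exhaustion and Th17 lists had medians of 0.18, 0.19 and 0.19.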

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

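Of the 11 tests in this part, those of free RNA, scaling and sex mixture for Tmem173, of doublets and sort proportion for cluster 3, and of class make-up for interferon gamma genes were chosen after the result was seen. Signals outside the main measurement drew attention to 2 results. Cells with Xist and no Y-linked UMI were 4.27% of cells with a sex-linked UMI of 1 kind in WTKL and 2.22% in LYZKL. This gap differed by class, with 5.72% and 0.687% in CD8-like cells and 3.18% and 3.50% in cycling-like cells. A sex mixture was tested for Tmem173 only, not for cluster 3 or the gene lists. Cluster 17, which carries T cell and neutrophil markers together, held 0.212% of kept cells in WTKL and 2.06% in LYZKL. The size of this gap varies with the removal of doublets, 9.61% of cells in WTKL and 3.23% in LYZKL. With at least 200 detected genes, where 9.72% and 7.99% were removed, the matching cluster held 0.109% and 0.754%, with doublets kept the matching cluster held 3.16% and 4.23%, and at the preset rate in both libraries most of the cells of cluster 17 still present lay in a neutrophil-like cluster with 4.12% and 11.6%.

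Tmem173 was higher in LYZKL in Treg-like and CD4 conventional-like cells. Free RNA would raise CD8-like cells too, yet their log2 ratio was 0.054 with an upper bound of 0.26. That value pools CD8-like clusters whose shares differ between the libraries, so it cannot exclude a rise within single clusters. Other scalings left the Treg-like value at 1.35 or more, and cells with a Y-linked and no Xist UMI kept a value of 1.10 (0.90 to 1.29) over both classes, which argues against scaling and sex mixture as the whole cause. Linked strain background stays open: 0% of 56 genes within 5 Mb of Tmem173 differed by 1.5-fold the same way in Treg-like and CD4 conventional-like cells, but random windows have a median of 0% as well, and a variant acting on Tmem173 alone would not show. Genotype, the tamoxifen named for WTKL alone, and differences between single mice were not tested and may each contribute.

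Cluster 3 made up more of LYZKL. Removing doublets at the preset rate in both libraries left a log2 ratio of 1.67 (1.55 to 1.79), and clusters made without leading genes that differ between libraries gave 1.51 (1.40 to 1.62). The sort can set the proportion of CD8-like to CD4-type cells, but cluster 3 was also a larger share of CD8-like cells alone (0.98, 0.88 to 1.07). Such a proportion does not change that share if cluster 3 holds CD8 T cells. Its CD8 name is in doubt, so the sort is not excluded. Genotype and the tamoxifen named for WTKL alone stay open as untested explanations, with 1 library per group, and so does the spread between mice.

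Interferon gamma response genes were higher in LYZKL in Treg-like, CD4 conventional-like and B-like cells. Other scalings left the Treg-like median at 0.65 or more, which argues against scaling in that class. Within CD4 conventional-like clusters 1 and 5 the lower median was 0.45 (lower bound 0.39), which argues against class make-up as the whole cause there. In the unnamed clusters 2 and 9, which lie closest to that class, the medians were 0.16 and 0.10. Treg-like and B-like cells form a single cluster each, so class make-up was not tested in them. Free RNA would reach CD8-like clusters 3, 8 and 13, where the highest median was 0.046 (upper bound 0.16). A lower level of these clusters' own transcripts in LYZKL could hide added RNA, so free RNA is not excluded. Without the 10% of Treg-like cells of each library with the highest share of these genes the median was 0.87 (0.70 to 0.93). This argues against a rise carried only by those cells. Because the cut takes an equal part of each library, it cannot exclude a responding part of the cells that is larger in LYZKL. Genotype, the tamoxifen named for WTKL alone, and differences between single mice remain untested, and any of them could underlie the pattern.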

How the results depend on the processing

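The additions made after the data were seen are doublets at the preset rate in both libraries, unnamed clusters counted with their closest class, single CD8-like clusters, and clusters without differing leading genes; the cause of the values below was not tested except where stated. No paired analysis was possible because each group has 1 library, and no threshold of a test applies. Values are log2 ratios, LYZKL over WTKL. The Foxp3-positive share (0.18 to 0.35 over 15 alternatives), the pro-apoptotic list (-0.064 to 0.024 over 19) and the NAD metabolism and P2X7 list (-0.27 to -0.022 over 19) stayed within their intervals in every alternative run. Of 1834 values of named genes under alternatives, 1441 stayed within their intervals, 370 moved and 23 turned direction. Depth limits what can be said of weakly expressed genes such as Art2b.

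The CD8-like share turned to -0.57 with at least 1000 detected genes, -0.59 with doublets kept, -0.013 at resolution 2 and -2.31 with each library clustered alone. In these settings 95.5%, 98.2%, 78.0% and 68.4% of the cells of cluster 3 lay in clusters left unnamed, which lowers the share in LYZKL most, and counting closest classes gave 0.17 to 0.79 over 13 settings. With each library clustered alone the unnamed part of cluster 3 was 2.47% in WTKL and 85.8% in LYZKL. All CD8-like values of that setting below thus compare unlike cells. By marker UMIs the share was 0.34, and with closest classes 0.54.

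The CD4 conventional-like share was -0.33 with 4000 variable genes, -0.19 at resolution 2, -0.18 by marker UMIs, -0.24 with each library alone, -0.34 with closest classes and -0.38 without differing leading genes. The Treg-like share was 0.24 by Foxp3 UMIs, -0.13 with at least 1000 genes and -0.10 with up to 20% mitochondrial UMIs. The cycling-like share was 0.99 at resolution 0.5 and 0.42 with the preset doublet rate, where the non-T share was 0.12.

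In Treg-like cells the survival list was 0.0061 by Foxp3 UMIs, 0.15 with at least 1000 genes and 0.16 with up to 20% mitochondrial UMIs. The identity list was -0.034, 0.16 and 0.15 there, 0.10 with up to 5% and -0.035 with each library alone. By Foxp3 UMIs Foxp3 was -0.017, which follows from choosing cells by that gene, and Gzmb -0.19. The type I interferon list in T-lineage cells was 0.045 with the preset doublet rate, -0.0996 with no minimum for list genes and 0.028 with 20 CPM.

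In CD8-like cells the cytotoxicity and exhaustion lists were 0.48 and 0.59 at resolution 2, 0.43 and 0.54 with TMM scaling, 0.30 and 0.58 with at least 1000 genes, 0.13 and 0.44 with each library alone, 0.49 and 0.50 with the mean of per-cell CPM, and 0.48 and 0.59 without ribosomal protein and mitochondrially coded genes in the total. In clusters 3, 8 and 13 alone they were 0.089 and 0.073, 0.066 and 0.38, and 0.13 and 0.087, and the cytotoxicity list was 0.37 with doublets kept.

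Genes that turned direction in CD8-like cells were Cd8a (-0.12 at resolution 2, -0.40 with at least 1000 genes, -0.20 with doublets kept), Bcl2 (0.0077 with at least 1000 genes, 0.021 with doublets kept), Art2b (0.045 with at least 1000 genes) and, with each library alone, Styk1 (-0.10), Ccl3 (-1.11), Cd4 (-0.40) and Ifng (-0.47). Bcl2 in CD4 conventional-like cells was -0.058 with 4000 variable genes, -0.17 at resolution 2 and -0.021 with the preset doublet rate, Mcl1 in CD4 conventional-like cells was -0.0595, -0.064 and -0.026 there, and Ctla4 was -0.039 with each library alone. Ctla4 in macrophage- or monocyte-like cells was -0.14 with at least 1000 genes, -0.24 with up to 20% and -0.054 with up to 5% mitochondrial UMIs, and -0.13 with the preset doublet rate.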

Other observations

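B-like cells of LYZKL had fewer transcripts of dividing cells: all 19 measured cell cycle genes were lower (median log2 ratio -1.08, -1.25 to -0.67), with Mki67 at 104 and 49.3 CPM, Top2a, a topoisomerase, at 50.1 and 23.5 CPM and Ube2c at 47.7 and 7.82 CPM. Rgs13, a gene of germinal centre B cells, was at 61.1 and 18.05 CPM. Of 22 interferon gamma response genes 21 were higher (median 0.71, 0.58 to 0.91), such as Igtp (19.6 and 46.9 CPM) and Socs1, a feedback inhibitor of cytokine signalling (109 and 225 CPM). The Th17 and Th1 lists, which hold T cell genes, also had higher medians in B-like cells (0.77, 0.28 to 1.09, and 0.64, 0.38 to 1.11), and T cell RNA among B-like cells was not tested as a cause. B-like cells were 5.13% of kept cells in WTKL and 3.10% in LYZKL.

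In neutrophil-like cells 13 of 16 glycolysis genes were lower in LYZKL (median -0.25, -0.29 to -0.17), among them Hk2, hexokinase 2 (115 and 68.6 CPM), and the glucose transporter Slc2a1 (251 and 163 CPM), and all 21 interferon gamma response genes were higher (median 0.34, 0.27 to 0.40). Within clusters 4, 11 and 12 the glycolysis medians were -0.055, 0.0059 and -0.43 and the interferon gamma medians -0.17, -0.15 and 0.89, so the class values do not hold in every cluster. Signs of RNA quality, handling and T cell RNA differed as well: all 12 mitochondrially coded genes (median -0.38), 14 of 18 immediate early and heat shock genes (-0.27) and all 10 naive and central memory genes of T cells (-0.74) were lower in neutrophil-like cells, and the cause of these values was not tested. Car4 was at 30.2 and 2.08 CPM, Siglecf at 37.0 and 9.07 CPM and G0s2 at 2546 and 658 CPM, while Ccl2, a monocyte chemokine, was at 163 and 563 CPM. Cluster 4 held 34.7% and 67.8% of these cells and cluster 12 held 38.6% and 9.20%. Ccl2 is among the leading genes of cluster 4 and G0s2 among those of cluster 12, so their class values also depend on these shares. Cluster 16, led by Gzmb, Gzma and Klrg1, held 4.20% of T-lineage cells in WTKL and 0.456% in LYZKL. It lies closest to CD8 T cells but was left unnamed because its leading genes hold more NK cell markers.

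The remaining lists in Treg-like cells had medians of -0.048 for tissue residency, -0.30 for Th2, 0.062 for Th17, -0.38 for Tfh, -0.19 for T cell activation, 0.16 for the STING pathway, 0.22 for homing receptors, 0.059 for cell cycle, 0.0084 for glycolysis, 0.056 for oxidative phosphorylation, 0.13 for ribosomal proteins and -0.069 for sex-linked genes. Over all T-lineage cells the cell cycle list had 17 of 20 genes higher (median 0.29, 0.26 to 0.34) and the type I interferon list a median of -0.0022 (-0.084 to 0.022). Of 7571 genes measured, 2 differed by at least 2-fold the same way in 4 or more of 6 classes, 1 higher and 1 lower in LYZKL.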
